A study of Homo sapiens with 30 samples.

How the data were processed

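LNCaP cells, an established human prostate cancer line that depends on androgen, carried an shRNA against mTOR and were rescued through an inducible system, per the labels' protocols. The rescue was an empty vector (EV), wild-type mTOR (WT), mTOR with a nuclear export signal (NES), mTOR with a nuclear localization signal (NLS), or the nuclear form with the D2357E kinase-dead change (NLSKD). These 5 are called lines here. Cells were deprived of androgen for 48 h in medium with 2% charcoal-stripped serum, then given ethanol vehicle (0.1%) or 10 nM R1881, a synthetic androgen, for 24 h. Total RNA from 30 samples, 3 for each of the 10 groups, was sequenced as paired-end reads of 150 bases. The samples are described as triplicates and nothing in the labels says whether they were separate cultures, so every p-value measures the spread between these samples, which may be technical.

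The authors deposited, for each of 58735 genes and each library, a raw read count and an FPKM value (fragments scaled by gene length and sequencing depth), per the file headers. Per the submitters' processing notes, the tools were HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the genome build was hg38. The notes give no role or order for them, and the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of near-identical copies (UGT2B15, UGT2B17 and UGT2B28, ORM1 and ORM2, IFITM2 and its relatives, MAGEC1 and MAGEC2, KLK2 and KLK3) and of overlapping or antisense genes are therefore uncertain. The deposited FPKM was checked against the counts: in each library 100% of the genes with enough counts gave the same denominator to within 0.1%, and the count total divided by this denominator ran from 0.913 to 1.08 (median 0.987). All 58735 gene identifiers, starts and ends were those of GENCODE release 29. Of the symbols, 58708 were the same, 27 had been turned into dates, and 1568 were repeats of another gene's symbol, so genes were followed by identifier. Each line of the table named a gene, and no column of another sample was present.

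Library totals ran from 21.4 to 61.8 M counts. The 2 deepest were NES under R1881, replicate 1 (61.8 M) and NLS under R1881, replicate 1 (39.5 M). Intervals that rest on counts alone cover counting error only. Replicates of a group differed from each other by far more than sampling noise (chi-square per degree of freedom at least 12.7), so none was a repeat of another library. The share of counts from mitochondrially encoded genes ran from 3.90% to 11.7% and was above 9% in 5 libraries: EV vehicle 3, NLS vehicle 2, NLSKD vehicle 2, NES R1881 2 and NLS R1881 2.

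All tests used the raw counts in R 4.3.3. edgeR 4.0.16 (TMM factors, filterByExpr, glmQLFit and glmQLFTest, two-sided) was fitted once to all 30 libraries with 1 mean per group and no block, because 3 libraries per group alone estimate the spread poorly. The filter left 18296 genes, 13489 of them protein-coding, and 40439 were not tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Fold changes are log2 values with the standard error that the F statistic implies, and CPM values are means with the SD of 3 libraries. The 24 comparisons were the androgen response in each of the 5 lines, each of the 4 rescue lines against EV under each treatment, NLS against NES and NLS against NLSKD under each treatment, NES and NLS against WT under R1881, and 5 differences between androgen responses (interactions). Where a group had no count of a gene, the fold of the lowest library of the other group was computed against a floor of 3 counts over the group and is given as "at least". With 1 to 3 counts the ratio of the summed counts is given with its exact 95% counting interval.

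Named genes followed a rule. Per comparison these were the 10 highest and 10 lowest fold changes among called protein-coding genes with a mean CPM of at least 5 and no overlap between the groups' libraries (overlap was allowed for an interaction), up to 4 members per gene list by adjusted p, and always 7 genes fixed before the data were examined, of which MTOR, KLK3, KLK2, FKBP5 and TMPRSS2 appear in the text. Results of 3 genes, and 1 test of an explanation that rested on one of them, are not reported here. A pair of groups of 3 libraries does not overlap by chance for 10% of genes.

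The 27 gene lists covered androgen-induced and androgen-repressed genes, cholesterol synthesis, fatty acid synthesis, glycolysis, oxidative phosphorylation, the TCA cycle, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis, ATF4 targets with amino acid genes, nucleotide synthesis, lysosome and autophagy, G1/S and DNA replication, G2/M and mitosis, FOXO and PI3K feedback, the unfolded protein response, hypoxia, p53 targets, the interferon response, immediate early genes, heat shock, components of the mTOR complexes, and markers of neuroendocrine, luminal, basal and mesenchymal cells. They were written from general knowledge, not chosen on these samples. Some share members: the androgen-induced list shares 3 with the luminal and 1 with the hypoxia list, and the androgen-repressed list shares 1 with the luminal and 1 with the neuroendocrine list. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01), then with a correlation estimated from the data, and with fry, which asks whether a list's genes move one way and not how they compare with other genes. Members were also counted at p adjusted over the list alone. A list score is the mean log2 CPM of its members (prior count 2), with a 95% interval from the spread within groups (20 degrees of freedom).

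The groups, tests, naming rule and the following alternatives were fixed before the data were examined. They were DESeq2 1.42.0, RLE size factors, no filter beyond 1 count, a stricter filter (CPM of at least 1 in at least 3 libraries), the replicate number as a block, only the compared groups in the fit, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), and leaving out each library of a comparison in turn. The overlap of rescue effects was repeated at adjusted p 0.01 and the similarity of responses on genes with a CPM of at least 5. Alternatives added after the data were seen were thinning the 2 deepest libraries to 24.5 M counts, the mitochondrial share as a covariate, and a fit on the 25 libraries with a share up to 9%.

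Groups share replicate numbers in the labels, without a word on what a number marks. Deviations of same-numbered libraries from their group means correlated between -0.28 and 0.64 (median 0.18, above 0.1 in 94 of 135 pairs of libraries). The second principal component was higher in replicate 1 than in replicate 2 in 10 of 10 groups. In 10 of the 24 comparisons every pair was above 0.1 and the numbers were taken to pair the samples: the androgen responses in EV, WT, NES and NLSKD, NLS against EV under both treatments, NLSKD against EV under R1881, NLS against NES under R1881, NLS against NLSKD under vehicle and NLS against WT. For these the blocked count is given wherever it moved by over 1.5 times. For the other comparisons it is listed in the section on how the results depend on the processing.

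The code was tested on simulated counts with 200 changed genes of a mean CPM of at least 5. Every simulated group had the spread estimated over all 30 libraries and no effect of the replicate number, so recovery may be lower in groups that spread more. The tests below are of this kind. For NLS against NES under R1881, with 17849 genes, the code recovered 1.49% of the 1.5-fold, 49.3% of the 2-fold and 93.9% of the 4-fold changes, and 4.00% of its calls were false. For the interaction of NLS against NES, with 17858 genes, it recovered 0% of the 1.5-fold, 19.4% of the 2-fold and 92.4% of the 4-fold changes, and 9.76% of its calls were false. In the simulation of NLS against NES under R1881 camera in limma called the seeded list and 0 of 26 unchanged lists. Genes were simulated independently and the unchanged lists were drawn at random. The 0 therefore says nothing about false calls on real lists, whose members move together. The median standard error of genes with a CPM of at least 5 was 0.24 on the log2 scale for NLS against NES under R1881 and 0.34 for the interaction of these lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.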

Results

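Gene expression was measured in 30 samples of LNCaP prostate cancer cells in which mTOR, the kinase of the growth-controlling mTOR complexes, was knocked down and replaced. The replacement was an empty vector (EV), wild-type mTOR (WT), mTOR with a nuclear export signal (NES), mTOR with a nuclear localization signal (NLS) or its kinase-dead D2357E form (NLSKD), and each line received vehicle or the androgen R1881, with 3 samples per group. Library totals ran from 21.4 to 61.8 M counts, and 18296 of 58735 genes were tested. The first 3 principal components held 23.2%, 17.0% and 13.6% of the variance. The share of mitochondrially encoded counts had its highest group mean in NLSKD under vehicle (8.45%) and was 7.17% in EV under vehicle.

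MTOR (ENSG00000198793, hg38 chromosome 1, 11106535 to 11262507) was lowest in EV and highest in NES. Under R1881 its level was 66.1 ± 9.54 CPM in EV, 1603 ± 183 in WT, 4296 ± 1398 in NES, 1037 ± 362 in NLS and 1082 ± 365 in NLSKD (SD, n = 3 each). Under vehicle the levels were 25.7 ± 4.86, 1840 ± 276, 5252 ± 2028, 930 ± 290 and 1016 ± 426 CPM in the same order. Against EV under R1881 MTOR was higher by a log2 fold change of 4.60 ± 0.38 in WT, 6.02 ± 0.40 in NES, 3.97 ± 0.37 in NLS and 4.03 ± 0.37 in NLSKD (standard error throughout for fold changes), and all 8 tests of MTOR against EV under both treatments passed. Gene counts cannot tell construct reads from the cells' own MTOR, and no library without the shRNA was analysed here. Within EV, R1881 raised MTOR by 1.36 ± 0.33 (edgeR adjusted p = 0.00786), and no change passed in WT (-0.20 ± 0.32, adjusted p = 0.845), NES, NLS or NLSKD.

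**Figure D1:**
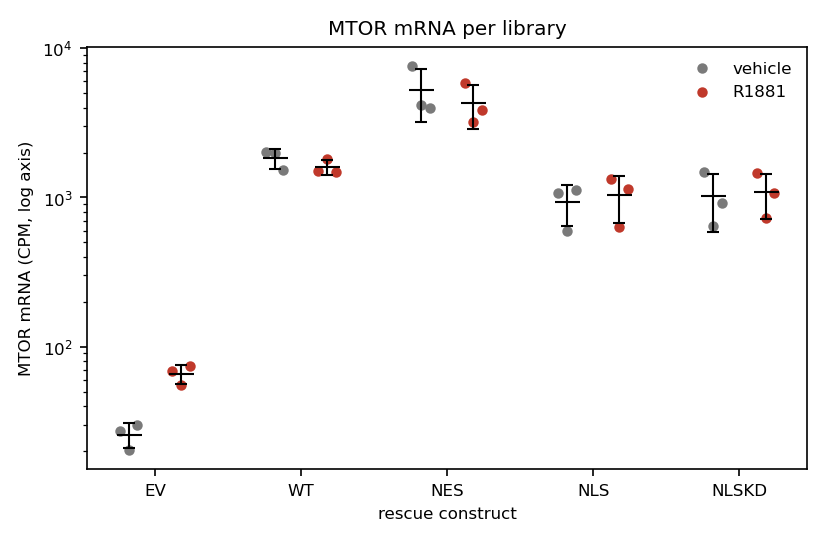
MTOR level (CPM, log axis) in each of the 30 libraries by line (horizontal axis) and treatment (colour), with points for libraries and black lines for the group mean and SD. The EV libraries lie lowest, with group means of 25.7 CPM under vehicle and 66.1 CPM under R1881, and NES has the highest means.

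The first question was what androgen changed in each line. In EV, R1881 raised genes that had 0 or few counts under vehicle. SLC38A4, an amino acid transporter (ENSG00000139209, chromosome 12, 46764761 to 46832408), went from 0 counts to 22.0 ± 7.62 CPM, at least 347-fold, the glucose transporter SLC2A3 to 17.4 ± 6.71 CPM, at least 254-fold, and ORM2 to 11.3 ± 1.35 CPM, at least 233-fold. CCDC141 rose from 0.0274 to 28.0 CPM, a ratio of 1006 (counting interval 278 to 8309), and the metalloreductase STEAP4 by 9.72 ± 0.62. The genes that fell included SI (-5.37 ± 0.72), the opioid receptor OPRK1 (-4.25 ± 0.36), LRRC31 (-4.01 ± 0.50) and LRRN1 (-3.81 ± 0.31). Known androgen targets rose together: KLK3, which encodes prostate-specific antigen, by 1.93 ± 0.32 (450 ± 222 to 1713 ± 264 CPM), KLK2 by 3.21 ± 0.26, the protease gene TMPRSS2 by 3.92 ± 0.22 and FKBP5, an HSP90 co-chaperone, by 4.96 ± 0.27.

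Of the 56 androgen-induced genes 50 rose in EV over all genes tested and 54 adjusted over the list alone, led by PMEPA1 (3.56 ± 0.15) and SLC45A3 (4.47 ± 0.20). Of 14 androgen-repressed genes 12 fell and 1 rose over all genes, with 12 falling adjusted over the list alone, led by the chemokine receptor ACKR3 (-3.57 ± 0.27) and OPRK1. Of 24 cholesterol synthesis genes 14 rose (17 adjusted over the list alone), among them FDFT1 (2.83-fold, standard error 0.19 in log2) and INSIG1 (1.57 ± 0.29). Of 33 interferon response genes 6 fell and 1 rose (7 fell adjusted over the list alone), led by CMPK2 (2.83-fold lower, standard error 0.30 in log2) and IFIT2 (-1.46 ± 0.31). With an estimated correlation the adjusted p of these lists was 2.4e-06, 0.00045, 0.0063 and 0.023. In all, 1666 genes were called in EV, 833 higher and 833 lower.

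In WT, R1881 raised STEAP4 to 34.0 ± 13.1 CPM from 0 counts (at least 596-fold), SLC38A4 at least 616-fold, CCDC141 by 9.24 ± 0.87 and SLC2A3 by a ratio of 408 (counting interval 113 to 3376). AMIGO2 (-4.71 ± 0.39), SI (-4.30 ± 0.66) and the mannosidase MAN1A1 (-4.20 ± 0.53) fell. KLK3 rose by 2.97 ± 0.33, KLK2 by 4.61 ± 0.28, TMPRSS2 by 4.37 ± 0.23 and FKBP5 by 4.20 ± 0.26. Among the 56 androgen-induced genes 50 rose (52 adjusted over the list alone, adjusted p = 1.5e-06 with an estimated correlation). Among the 14 repressed genes 10 fell and 1 rose (11 fell adjusted over the list alone, adjusted p = 0.0073). Among the 24 cholesterol genes 8 rose (15 adjusted over the list alone, adjusted p = 0.024). The test called 1186 genes, 635 higher and 551 lower, and 1894 with the replicate number as a block.

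In NES, SLC38A4 rose at least 622-fold and SLC2A3 at least 319-fold from 0 counts, STEAP4 by 9.54 ± 0.68, CCDC141 by 9.11 ± 0.86 and the kinase anchor AKAP12 by 7.09 ± 0.79. AMIGO2 (-5.04 ± 0.39), SI (-4.85 ± 0.71) and OPRK1 (-4.16 ± 0.35) fell. KLK3 rose by 1.91 ± 0.32 (1389 ± 281 to 5210 ± 808 CPM), KLK2 by 3.95 ± 0.27, TMPRSS2 by 4.12 ± 0.22 and FKBP5 by 4.39 ± 0.26. Among the 56 androgen-induced genes 49 rose (52 adjusted over the list alone, adjusted p = 3.7e-06 with an estimated correlation). Among the 14 repressed genes 11 fell and 2 rose (12 fell adjusted over the list alone, adjusted p = 0.0025). Among the 24 cholesterol genes 11 rose (16 adjusted over the list alone, adjusted p = 0.028). In all 1510 genes were called, 770 higher and 740 lower. The count was 2495 with the replicate number as a block and 836 when the fit held these 2 groups only.

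In NLS, CCDC141 rose from 0 counts to 38.5 ± 28.0 CPM, at least 299-fold, SLC38A4 at least 220-fold from 0 counts, STEAP4 by 8.91 ± 0.67 and HPGD, which degrades prostaglandins, by 6.41 ± 0.72. AMIGO2 (-3.61 ± 0.36), SI (-3.34 ± 0.64) and MAN1A1 (-3.24 ± 0.50) fell. KLK3 rose by 2.77 ± 0.33, KLK2 by 4.44 ± 0.28, TMPRSS2 by 4.04 ± 0.22 and FKBP5 by 4.18 ± 0.26. Among the 56 androgen-induced genes 51 rose (55 adjusted over the list alone, adjusted p = 2.1e-07 with an estimated correlation). Among the 14 repressed genes 8 fell and 1, UGT2B28, rose (10 fell adjusted over the list alone, adjusted p = 0.028). Among the 24 cholesterol genes 4 rose (10 adjusted over the list alone, adjusted p = 0.045). Of 24 p53 targets 2 fell and 1 rose (3 fell adjusted over the list alone, adjusted p = 0.045), and of the 33 interferon response genes 0 were called (4 fell and 1 rose adjusted over the list alone, adjusted p = 0.046). In all 813 genes were called, 509 higher and 304 lower. The count was 208 when the fit held these 2 groups only and 508 without the libraries of high mitochondrial share.

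In NLSKD, CCDC141 rose at least 430-fold from 0 counts, STEAP4 by 9.55 ± 0.69, SLC38A4 by a ratio of 650 (counting interval 180 to 5373) and the acetylcholine receptor subunit CHRNA2 by 6.11 ± 0.35. AMIGO2 (-3.33 ± 0.36), SI (-3.13 ± 0.63) and MAN1A1 (-3.11 ± 0.50) fell. KLK3 rose by 3.14 ± 0.34, KLK2 by 4.84 ± 0.28, TMPRSS2 by 4.25 ± 0.22 and FKBP5 by 4.17 ± 0.26. Among the 56 androgen-induced genes 48 rose (53 adjusted over the list alone, adjusted p = 1.4e-07 with an estimated correlation). Among the 14 repressed genes 8 fell and 1 rose (10 fell adjusted over the list alone, adjusted p = 0.021). Among the 24 cholesterol genes 3 rose (15 adjusted over the list alone, adjusted p = 0.019). In all 746 genes were called, 454 higher and 292 lower.

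**Figure D2:**
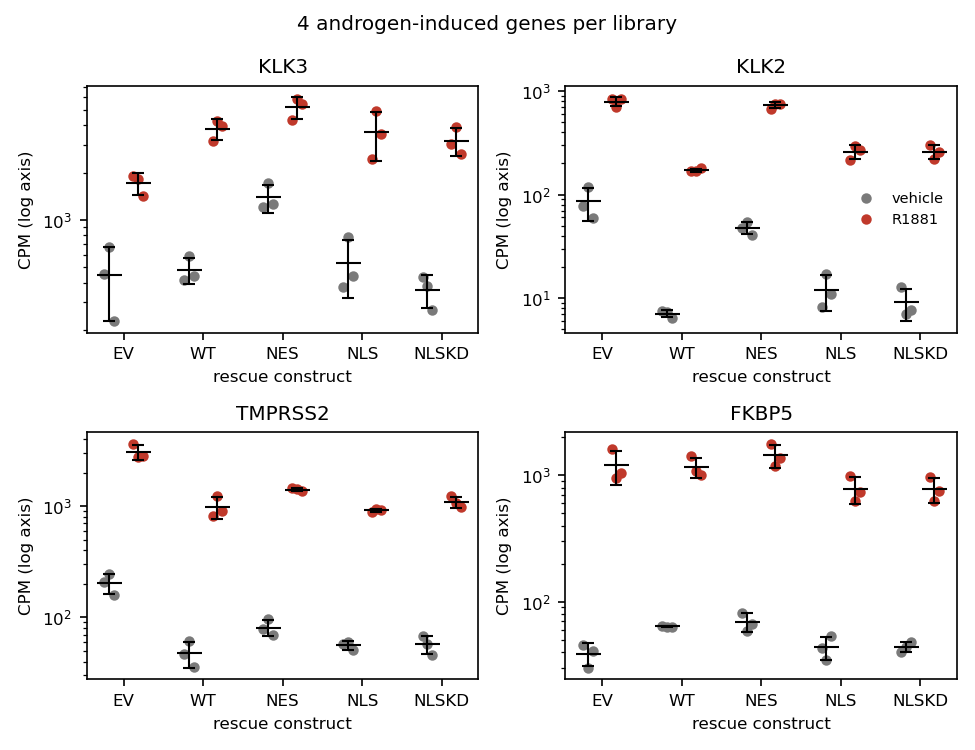
Level (CPM, log axis) of 4 androgen-induced genes in each library by line (horizontal axis) and treatment (colour), with points for libraries and black lines for the group mean and SD. KLK3 rose from 450 to 1713 CPM in EV and from 1389 to 5210 CPM in NES.

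Across lines the androgen responses resembled each other. Correlations of log2 fold changes across the 18296 genes, which are not independent replicates, ran from 0.63 to 0.71, and from 0.82 to 0.93 over the 11077 genes with a CPM of at least 5. Regression slopes over these genes were 0.83 for WT, 0.91 for NES, 0.72 for NLS and 0.71 for NLSKD on EV, without a test. Noise in the EV response lowers such slopes, so they do not measure the size of a response. In all 5 lines 339 genes rose and 178 fell.

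The next question was how each rescue line differed from EV under R1881. In WT, CNTN5, a neuronal adhesion gene (ENSG00000149972, chromosome 11, 99020953 to 100358885), was higher by a ratio of 267 (counting interval 91.1 to 1298), the ephrin receptor EPHA3 by 6.95 ± 0.60 (320 ± 57.9 against 2.59 ± 0.662 CPM) and the glutamate receptor subunit GRIK2 by 5.30 ± 0.43. The RNA-binding protein gene NOVA1 (-6.66 ± 0.43), SDK1 (-6.46 ± 0.64) and the transcription factor gene RFX6 (-6.37 ± 0.45) were lower. KLK3 was higher by 1.14 ± 0.31 (adjusted p = 0.0204), and TMPRSS2 (-1.64 ± 0.20) and KLK2 (-2.21 ± 0.25) were lower. Of the 56 androgen-induced genes 20 were lower and 1 higher (26 lower adjusted over the list alone), led by ALDH1A3 (-3.82 ± 0.24), but with an estimated correlation the adjusted p was 0.10. Of the 14 androgen-repressed genes 9 were higher and 1 lower (10 higher adjusted over the list alone, adjusted p = 0.017 with an estimated correlation), led by UGT2B17 (4.26 ± 0.30), which conjugates androgens. Of 35 DNA replication genes 15 were higher (27 adjusted over the list alone), with MCM4 at 1.04 ± 0.17, and the adjusted p was 0.060 with an estimated correlation. Of 19 hypoxia genes 5 were lower (10 adjusted over the list alone, adjusted p = 0.044 with an estimated correlation), led by EGLN3 (-1.55 ± 0.18). In all 1553 genes were called, 669 higher and 884 lower, and 1035 without WT R1881 replicate 3.

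In NES against EV under R1881, MTOR was higher, as were KLF7 (4.22 ± 0.32), SLC22A2 (4.18 ± 0.72) and GRIK2 (3.70 ± 0.41). FAM110B was lower by a ratio of 437 (counting interval 149 to 2125), and the potassium channel gene KCNJ3 (-8.23 ± 0.68), SDK1 (-8.22 ± 0.71) and RFX6 (-7.29 ± 0.48) were lower. KLK3 was higher by 1.60 ± 0.32 (adjusted p = 0.00164), TMPRSS2 was lower (-1.13 ± 0.20), and KLK2 gave -0.12 ± 0.24 (adjusted p = 0.868). Of the 14 androgen-repressed genes 6 were higher and 1 lower (8 higher adjusted over the list alone), with UGT2B17 at 2.37 ± 0.27. Of 35 DNA replication genes 16 were higher (26 adjusted over the list alone), with MCM4 at 0.95 ± 0.17. With an estimated correlation the adjusted p of these lists was 0.11 and 0.078. Of the 33 interferon response genes 4 were lower and 1 higher (8 lower adjusted over the list alone, adjusted p = 0.011 with an estimated correlation), led by IFIT2 (-1.60 ± 0.32). In all 1273 genes were called, 598 higher and 675 lower. The count was 788 without EV R1881 replicate 3, 819 without NES R1881 replicate 2 and 723 without NES R1881 replicate 3.

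In NLS against EV under R1881, the neuronal membrane gene SLITRK5 (ENSG00000165300) was at 10.4 ± 2.19 CPM against 0 counts, at least 195-fold higher, EPHA3 was higher by 5.62 ± 0.57 and GRIK2 by 4.73 ± 0.42. RFX6 (-5.48 ± 0.43), SDK1 (-4.86 ± 0.57) and FAM110B (-4.50 ± 0.54) were lower. KLK3 was higher by 1.08 ± 0.31 (adjusted p = 0.0365), and TMPRSS2 (-1.75 ± 0.20) and KLK2 (-1.61 ± 0.24) were lower. Of the 56 androgen-induced genes 23 were lower and 1 higher (35 lower adjusted over the list alone, adjusted p = 0.011 with an estimated correlation), led by ALDH1A3 (-3.38 ± 0.23). Of the 14 androgen-repressed genes 9 were higher and 1 lower (9 higher adjusted over the list alone, adjusted p = 0.0047), led by UGT2B17 (3.89 ± 0.29) and the dopa decarboxylase gene DDC (3.43 ± 0.25). Of 39 ATF4 targets, which serve amino acid supply, 10 were higher and 1 lower (20 higher adjusted over the list alone, adjusted p = 0.016): the amino acid transporter SLC7A5 was lower (-2.78 ± 0.30), and TRIB3 (0.92 ± 0.14), SLC1A4 (1.68 ± 0.26) and the serine synthesis gene PSPH (0.68 ± 0.12) were higher. In all 1139 genes were called, 510 higher and 629 lower, 1953 with the replicate number as a block and 245 when the fit held these 2 groups only. The count was 744 without EV R1881 replicate 3 and 748 without NLS R1881 replicate 3. limma on log2(FPKM + 1) gave 391 higher and 817 lower.

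In NLSKD against EV under R1881, EPHA3 (5.61 ± 0.57), SLC22A2 (4.59 ± 0.73), GRIK2 (4.50 ± 0.42) and PEG3 (4.46 ± 0.40) were higher, and RFX6 (-4.79 ± 0.41), FAM110B (-4.07 ± 0.53) and PALMD (-3.77 ± 0.33) were lower. TMPRSS2 (2.83-fold, standard error 0.20 in log2) and KLK2 (-1.61 ± 0.24) were lower, and KLK3 gave 0.89 ± 0.31 (adjusted p = 0.0999). Of the 56 androgen-induced genes 19 were lower (33 adjusted over the list alone, adjusted p = 0.018 with an estimated correlation), led by ALDH1A3 (-2.91 ± 0.23). Of the 14 androgen-repressed genes 8 were higher and 1 lower (10 higher adjusted over the list alone, adjusted p = 0.0015), led by UGT2B17 (4.04 ± 0.29) and DDC (3.30 ± 0.25). Of the 39 ATF4 targets 13 were higher and 1 lower (18 higher adjusted over the list alone, adjusted p = 0.0075), with SLC7A5 at -2.81 and TRIB3 at 0.99 ± 0.14. In all 1052 genes were called, 513 higher and 539 lower, 1833 with the replicate number as a block and 548 when the fit held these 2 groups only. The count was 675 without EV R1881 replicate 1, 688 without EV R1881 replicate 3 and 676 without NLSKD R1881 replicate 3. limma on log2(FPKM + 1) gave 430 higher and 828 lower.

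The rescue lines had called genes in common. Under R1881, 444 genes were called in the same direction in all 4 lines, 185 higher and 259 lower, out of 2364 called in any. WT and NLS had 347 genes higher and 492 lower in common, where independent lists would share 18.6 and 30.4. NLS and NLSKD had 362 higher and 437 lower, where 14.3 and 18.5 would be shared. NES and NLSKD had 228 higher and 302 lower, where 16.8 and 19.9 would be shared, and 8 genes called in opposite directions, as were 9 for WT and NES. In 20 simulations of unchanged lines measured against the same EV libraries each pair shared 0 and 0, which decides nothing because unchanged lines have hardly any calls to share. The covariance of fold changes ran over the 6 pairs from 0.51 (NES and NLSKD) to 0.68 (WT and NLS, WT and NES), against 0.15 in the simulations. The share of genes with the same sign was 67.8% for NES and NLSKD against 66.9% in the simulations, and 80.3% against 66.8% for NLS and NLSKD. Part of the excess overlap may come from these shared libraries, which are too few to split.

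Under vehicle the rescue lines also differed from EV, beside MTOR. In WT, CNTN5 (7.76 ± 0.94) and EPHA3 (5.74 ± 0.56) were higher, RFX6 was lower by a ratio of 1313 (counting interval 235 to 51899), and KLK2 (-3.60 ± 0.27) and TMPRSS2 (-2.09 ± 0.20) were lower. In NES, SLC22A2 (4.11 ± 0.70), KLF7 (3.91 ± 0.31), KLK3 (1.63 ± 0.32, adjusted p = 0.00158) and FKBP5 (0.83 ± 0.23, adjusted p = 0.0312) were higher. SPAG16 was lower in NES by a ratio of 886 (counting interval 159 to 35029), RFX6 by 411 (140 to 1994), and KCNJ3 (-7.92 ± 0.62), TMPRSS2 (-1.33 ± 0.20) and KLK2 (-0.85 ± 0.24, adjusted p = 0.0361) were lower. In NLS, SLITRK5 (7.88 ± 0.61) and CNTN5 (5.98 ± 0.91) were higher, CLSTN2 was lower by a ratio of 777 (counting interval 139 to 30706), and RFX6 (-7.86 ± 0.57), KLK2 (-2.84 ± 0.26) and TMPRSS2 (-1.86 ± 0.20) were lower. In NLSKD, SLITRK5 (7.80 ± 0.61), SLC22A2 (4.65 ± 0.71) and PCDH7 (4.46 ± 0.35) were higher, CLSTN2 was lower by a ratio of 404 (counting interval 112 to 3345), and RFX6 (-5.60 ± 0.46), KLK2 (-3.24 ± 0.26) and TMPRSS2 (-1.83 ± 0.20) were lower. The luminal marker list was lower in WT, NLS and NLSKD with 5, 4 and 5 of 14 members called lower (6, 4 and 5 adjusted over the list alone, adjusted p = 0.010, 0.0055 and 0.00031 with an estimated correlation). The interferon list was lower in WT, NES and NLSKD with 2, 4 and 0 of 33 called (2, 6 and 0 adjusted over the list alone, adjusted p = 0.019, 0.0011 and 0.044), and in NLS its adjusted p was 0.14. In NES the heat shock list was higher with 3 of 15 called (5 adjusted over the list alone, adjusted p = 0.043), led by DNAJB1 (0.58 ± 0.13).

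Under vehicle 1228 genes were called in WT (421 higher, 807 lower), 904 in NES (342 higher, 562 lower), 836 in NLS (290 higher, 546 lower) and 733 in NLSKD (269 higher, 464 lower), and 347 in all 4. For NES the count was 355 when the fit held these 2 groups only and 557 without NES vehicle replicate 3. For NLS it was 1571 with the replicate number as a block, 472 with these 2 groups only, 391 without the libraries of high mitochondrial share, and 547 without EV vehicle replicate 3. It was 550 without NLS vehicle replicate 1 and 546 without NLS vehicle replicate 2. For NLSKD it was 373 without the libraries of high mitochondrial share, 450 without NLSKD vehicle replicate 2 and 432 without NLSKD vehicle replicate 3.

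**Figure D3:**
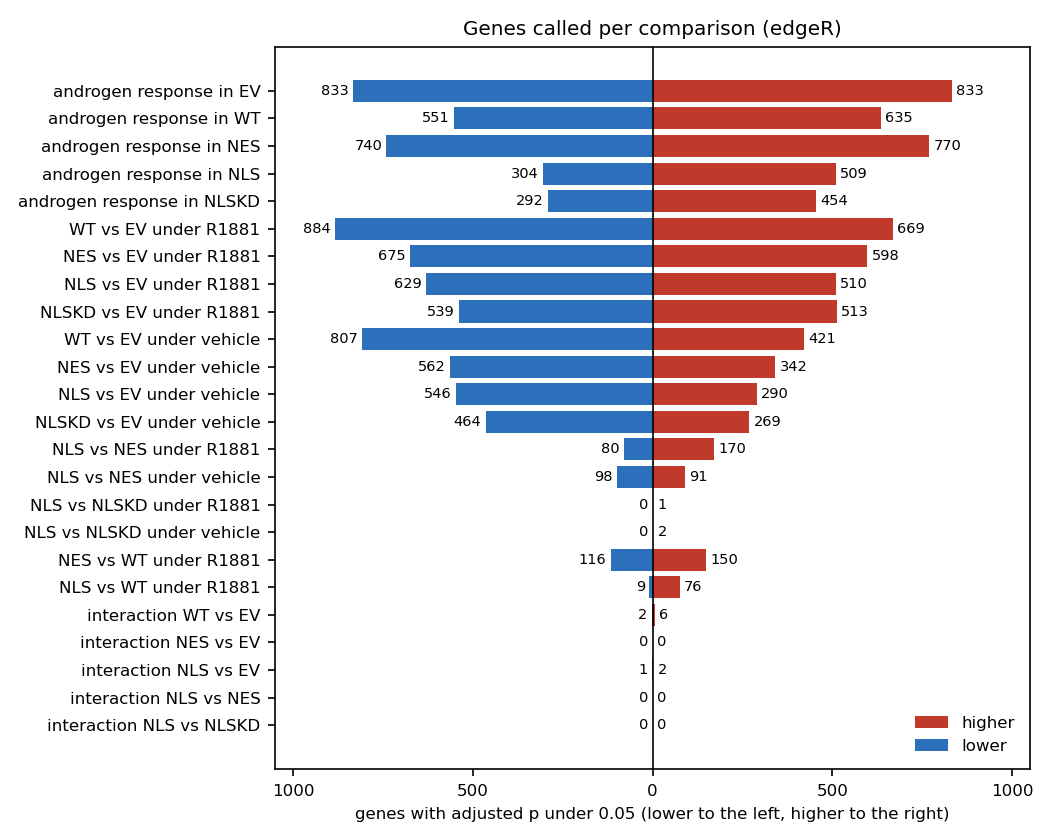
Number of genes called by edgeR at an adjusted p under 0.05 in each of the 24 comparisons, with bars to the right for higher and to the left for lower. The androgen response in EV has the most, 1666 genes, and interactions have 8 or fewer.

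The location of mTOR was compared directly as NLS against NES. Under R1881 the organic cation transporter SLC22A3 (ENSG00000146477, chromosome 6, 160348268 to 160452581) was higher in NLS by 3.85 ± 0.59 (9.80 ± 2.31 against 0.682 ± 0.127 CPM), SLITRK5 by 2.87 ± 0.41 and the cholinesterase gene BCHE by 2.79 ± 0.47. TMEM45B (-2.97 ± 0.27), the prostatic acid phosphatase gene ACPP (-2.58 ± 0.24) and RUNX1 (-2.23 ± 0.37) were lower, as were MTOR (-2.05 ± 0.34) and KLK2 (-1.49 ± 0.24, adjusted p = 0.000808). KLK3 did not pass (-0.52 ± 0.31, adjusted p = 0.709). Of the 39 ATF4 targets 12 were higher (24 adjusted over the list alone, adjusted p = 2.1e-05 with an estimated correlation), led by TRIB3 (0.98 ± 0.14), the seryl-tRNA synthetase gene SARS (0.80 ± 0.12) and PSPH (0.78 ± 0.12). Of the 14 androgen-repressed genes 5 were higher (7 adjusted over the list alone, adjusted p = 0.019), led by BCHE, OPRK1 (1.90 ± 0.32) and UGT2B17 (1.52 ± 0.26). Luminal markers were lower with 2 of 14 called (3 adjusted over the list alone, adjusted p = 0.019), and heat shock genes with 0 of 15 called (0 adjusted over the list alone, adjusted p = 0.019). Interferon response genes were higher with 1 of 33 called (3 adjusted over the list alone, adjusted p = 0.0034). The called member was UBE2L6, at a low level (1.88 ± 0.305 against 0.702 ± 0.0772 CPM). In all 250 genes were called, 170 higher and 80 lower. The count was 541 with the replicate number as a block, 5 with these 2 groups only, 477 by DESeq2, 109 without the libraries of high mitochondrial share, 138 without NES R1881 replicate 2, 132 without NES R1881 replicate 3 and 164 without NLS R1881 replicate 3. limma on log2(FPKM + 1) gave 112 higher and 142 lower.

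Under vehicle NLS exceeded NES in KCNJ3 (4.76 ± 0.58), CNTN5 (3.67 ± 0.75) and SLC22A3 (3.12 ± 0.57). TMEM45B (-2.88 ± 0.27), MTOR (-2.50 ± 0.34) and ACPP (-2.48 ± 0.24) were lower. Also lower were KLK2 (-1.99 ± 0.25) and KLK3 (-1.39 ± 0.32, adjusted p = 0.0247). Of the 39 ATF4 targets 13 were higher (27 adjusted over the list alone, adjusted p = 1.3e-05 with an estimated correlation), led by TRIB3 (1.19 ± 0.14) and the tryptophanyl-tRNA synthetase gene WARS (0.68 ± 0.13). Of 39 mitosis genes 4 were lower (36 adjusted over the list alone, adjusted p = 0.024), led by the kinetochore gene NDC80 (-1.07 ± 0.21) and CDK1 (-0.85 ± 0.20). Of 15 heat shock genes 2 were lower (7 adjusted over the list alone, adjusted p = 0.0037), DNAJA1 (-0.62 ± 0.14) and HSPH1 (-1.05 ± 0.25). Luminal markers were lower with 3 of 14 called (6 adjusted over the list alone, adjusted p = 0.0067), and interferon response genes higher with 0 of 33 called (0 adjusted over the list alone, adjusted p = 0.0095). In all 189 genes were called, 91 higher and 98 lower, and more with the replicate number as a block, as listed further below. The count was 311 without a filter, 11 with these 2 groups only, 394 by DESeq2, 295 with the mitochondrial share as a covariate, 106 (67 higher, 39 lower) without the libraries of high share, 119 without NES vehicle replicate 1, 103 without NES vehicle replicate 3, 76 without NLS vehicle replicate 1 and 113 without NLS vehicle replicate 2.

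Kinase activity of the nuclear form was compared as NLS against NLSKD. Under R1881 1 gene was called by edgeR: the cancer-testis gene MAGEC1 (ENSG00000155495, chromosome X, 141903894 to 141909388), higher in NLS by 2.47 ± 0.32 (11.1 ± 3.42 against 2.00 ± 0.571 CPM, adjusted p = 0.000913). Under vehicle MAGEC1 was higher by 2.25 ± 0.32 (adjusted p = 0.00414), with MAGEC2, named after its values were seen, at 1.45 (adjusted p = 0.00764). MTOR gave -0.06 ± 0.32 under R1881 and -0.13 ± 0.32 under vehicle, and KLK3 0.19 ± 0.31 under R1881. The score of the ATF4 targets differed by -0.065 (95% interval -0.20 to 0.073), of the androgen-repressed genes by -0.14 (-0.65 to 0.37) and of the androgen-induced genes by -0.10 (-0.42 to 0.22) on the log2 scale. No list was called under R1881 without a block. Under vehicle mitosis genes were called with the preset correlation but not with an estimated correlation (adjusted p = 0.64), and the unfolded protein response was called lower only with the replicate number as a block (adjusted p = 0.037, against 0.10 without). At an unadjusted p under 0.05 there were 357 genes under R1881 and 298 under vehicle. On simulated counts with 17860 genes the R1881 test recovered 98.5% of 4-fold, 43.3% of 2-fold and 5.97% of 1.5-fold changes. The simulation gave these lines the spread pooled over all groups. Replicates 1 and 2 of NLS under R1881 lay far apart on the second principal component (66.5 and -68.2), so recovery on the real libraries may be lower. The R1881 count was 9 without a filter, 0 with these 2 groups only, 3 by DESeq2, 2 by limma on log2(FPKM + 1) and 3 with the mitochondrial share as a covariate. The vehicle count of 2 became 5 with the replicate number as a block, 13 without a filter, 0 with these 2 groups only, 4 by DESeq2, 1 without the libraries of high mitochondrial share, 0 without NLSKD vehicle replicate 2 and 1 without NLS vehicle replicate 1 or 3 or NLSKD vehicle replicate 1 or 3.

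Against WT under R1881, NES was higher in NOVA1 (5.99 ± 0.43), CLU (3.77 ± 0.27) and PARVA (3.65 ± 0.34), lower in CNTN5 (-5.27 ± 0.82) and EPHA3 (-3.97 ± 0.51), and higher in MTOR (1.42 ± 0.33, adjusted p = 0.022) and KLK2 (2.09 ± 0.25). Of the 14 androgen-repressed genes 4 were lower and 1 higher (7 lower adjusted over the list alone), with an adjusted p = 0.12 with an estimated correlation. Of the 39 ATF4 targets 0 were called (5 lower adjusted over the list alone), with a median of -0.31 and an adjusted p = 0.087 with an estimated correlation. In all 266 genes were called, 150 higher and 116 lower. The count was 446 by DESeq2, 154 without the libraries of high mitochondrial share, 137 without WT R1881 replicate 1, 152 without WT R1881 replicate 3, 177 without NES R1881 replicate 1, 140 without NES R1881 replicate 2 and 138 without NES R1881 replicate 3. limma on log2(FPKM + 1) gave 192 higher and 96 lower.

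Against WT under R1881, NLS was higher in SLC22A3 (4.61 ± 0.63), the Wnt secretion gene WLS (2.47 ± 0.29) and PAGE1 (2.33 ± 0.41), and lower in SLC22A10 (-1.32 ± 0.28), PPM1A (-1.03 ± 0.23) and TMTC4 (-0.89 ± 0.18). MTOR gave -0.63 ± 0.33 (adjusted p = 0.902). Of the 39 ATF4 targets 1, TRIB3 (0.93 ± 0.14), was higher (6 adjusted over the list alone, adjusted p = 0.019 with an estimated correlation). Neuroendocrine markers were higher with 1 of 6 called (2 adjusted over the list alone, adjusted p = 0.032). In all 85 genes were called, 76 higher and 9 lower. The count was 215 (154 higher, 61 lower) with the replicate number as a block, 155 without a filter, 4 with these 2 groups only, 180 by DESeq2, 47 without WT R1881 replicate 1 or replicate 2 and 29 without WT R1881 replicate 3. limma on log2(FPKM + 1) gave 42 higher and 14 lower.

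Whether the androgen response itself differed between lines was tested as interactions. Between WT and EV 8 genes passed. Among them IGFBP3, which binds insulin-like growth factors (2.51 ± 0.43, adjusted p = 0.0142), BCL11B, named after its values were seen (2.42 ± 0.47), ACKR3 (2.04 ± 0.35), MEIS1 (1.82 ± 0.35) and KCNN2 (1.43 ± 0.24) had a more positive response in WT. The cytokine signalling inhibitor SOCS2 (-1.51 ± 0.26) and CRISPLD2 (-2.20 ± 0.33) had a more negative one. Both rose in both lines, SOCS2 from 19.9 to 52.0 CPM in WT and from 8.49 to 63.1 CPM in EV. CRISPLD2 went from 15.3 to 20.2 CPM in WT and from 4.09 to 24.8 CPM in EV. ACKR3 fell from 233 to 80.7 CPM in WT and from 143 to 12.1 CPM in EV. KCNN2 rose from 30.3 to 216 CPM in WT and from 173 to 458 CPM in EV. IGFBP3 rose from 3.74 to 8.81 CPM in WT and fell from 5.96 to 2.46 CPM in EV. The count was 24 without a filter, 2 with these 4 groups only, 26 by DESeq2 and 20 by limma on log2(FPKM + 0.1), with 55 higher and 45 lower on log2(FPKM + 1). It was 4 without EV vehicle replicate 1, EV R1881 replicate 2 or WT R1881 replicate 1, 2 without EV vehicle replicate 3, WT vehicle replicate 2 or WT R1881 replicate 3, and 1 without WT vehicle replicate 3 or EV R1881 replicate 1.

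Between NLS and EV 3 genes passed: ACKR3 (2.36 ± 0.35, adjusted p = 0.00768) fell from 164 to 70.6 CPM in NLS and from 143 to 12.1 CPM in EV. UGT2B17 responded more positively in NLS (2.11 ± 0.37, adjusted p = 0.0367) and CRISPLD2 more negatively (-1.87 ± 0.33). The androgen-repressed list had a median difference of 1.38, with 2 of 14 members higher over all genes and 10 adjusted over the list alone (adjusted p = 0.0028 with an estimated correlation). The count was 38 without a filter, 0 with these 4 groups only, 24 by DESeq2, 19 by limma on log2(FPKM + 0.1) with 51 higher and 42 lower on log2(FPKM + 1), 8 with the mitochondrial share as a covariate, and 1 with RLE factors, with thinned libraries or without the libraries of high share. It was 0 without EV vehicle replicate 1, EV R1881 replicate 1 or EV R1881 replicate 2, and 1 without any of the 3 NLS vehicle libraries, NLS R1881 replicate 1 or NLS R1881 replicate 3.

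In the other interactions edgeR called 0 genes without a block. With the replicate number as a block more genes were called for the interactions of WT, NES and NLS with EV, as listed further below. Between NES and EV 490 genes had an unadjusted p under 0.05, and DESeq2 called 2, edgeR without a filter 10 and limma 56 on log2(FPKM + 1) and 10 on log2(FPKM + 0.1). Between NLS and NES there were 403 at an unadjusted p under 0.05, with 1 call by DESeq2, 5 without a filter and 7 by limma on log2(FPKM + 1). Between NLS and NLSKD there were 147, with 4 calls without a filter and 0 by DESeq2 and by limma.

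**Figure D4:**
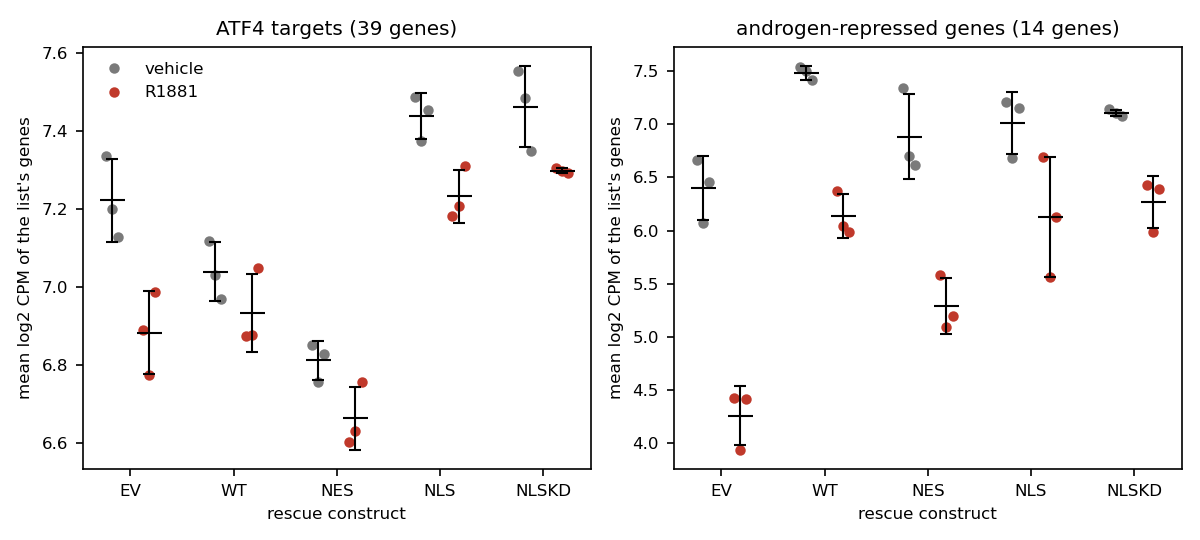
Score (mean log2 CPM of the members) of the ATF4 targets (39 genes) and the androgen-repressed genes (14 genes) in each library by line (horizontal axis) and treatment (colour), with points for libraries and black lines for the group mean and SD. Under R1881 the ATF4 score of NLS minus NLSKD was -0.065, with a 95% interval from -0.20 to 0.073.

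Over the 27 lists and 24 comparisons, 220 of 648 pairs were called with the preset correlation and 60 also with an estimated correlation. By list the calls with both were 7 for androgen-induced genes, 10 for androgen-repressed genes, 5 for cholesterol synthesis, 6 for ATF4 targets (5 higher, 1 lower), 1 for mitosis, 3 for hypoxia, 1 for p53 targets, 8 for the interferon response (2 higher, 6 lower), 3 for heat shock (1 higher, 2 lower), 3 for neuroendocrine markers and 13 for luminal markers (5 higher, 8 lower). With the preset correlation alone there were calls for DNA replication (16), glycolysis (11), nucleotide synthesis (9), the unfolded protein response (8), fatty acid synthesis (7), FOXO feedback (6), immediate early genes (6), mesenchymal markers (6), lysosome and autophagy (5), ribosome biogenesis (4), ribosomal proteins (3), mitochondrially encoded genes (2), oxidative phosphorylation (1) and the TCA cycle (1). Basal markers and components of the mTOR complexes were called in 0 comparisons. For the interferon response the estimated correlation was below the preset 0.01 (-0.0086 in NES against WT under R1881). It thus made no allowance for members that move together. Luminal markers were called higher in the androgen responses of EV, WT, NES, NLS and NLSKD, with 6, 5, 6, 3 and 5 of 14 rising and 1, 1, 0, 0 and 0 falling. Adjusted over the list alone 6, 6, 6, 5 and 6 rose and 2 fell in each (adjusted p = 0.0018, 0.00043, 0.0046, 0.00047 and 3.3e-05 with an estimated correlation). In NES they had a median of -0.09 and a mean of 0.73.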

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

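All tests of explanations in this part were chosen after the results were seen. Androgen responses that differed between lines, by a test of the difference itself, drew attention to 8 genes for WT against EV, 7 of them named here, and to 3 genes and 1 list for NLS against EV. For WT against EV the differences of response were 2.51 for IGFBP3, 2.42 for BCL11B, 2.04 for ACKR3, 1.82 for MEIS1, 1.43 for KCNN2, -1.51 for SOCS2 and -2.20 for CRISPLD2. For NLS against EV they were 2.36 for ACKR3, 2.11 for UGT2B17, -1.87 for CRISPLD2 and a median of 1.38 for the androgen-repressed list. Lists were taken here where the preset and the estimated correlation both called them, a criterion set after the values were seen.

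The androgen-repressed genes fell less in NLS than in EV, by 58.6% of the fall in EV. The list's median difference from the EV response was also positive in WT (0.90) and NES (0.39). Neither passed camera with an estimated correlation (adjusted p = 0.077 and 0.59), but the lean is not shown to be particular to NLS. A weaker androgen response as a whole would lower the induced genes as well, and their score differed by -0.15 (lower bound -0.61), above the bound of -0.74 set for a loss of this kind. A smaller loss over all genes stays open: the slope of the NLS response on that of EV was 0.72 over genes with a CPM of at least 5, without a test. The slope does not size such a loss, because noise in the EV response lowers it. Kinase activity of the nuclear form stays open: the NLS and NLSKD responses of the list differed by -0.044, with an upper bound of 0.68. A difference between the lines beside their construct was not tested and may account for the pattern.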

How the results depend on the processing

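The thinned libraries, the mitochondrial share as a covariate and the fit on 25 libraries were chosen after seeing the data. Over 28 counts and summaries, 416 of 547 values under an alternative were the same, 50 stronger, 77 weaker and 4 moved. Here the same means within 1.5 times for a count, and within the SD over pairs of lines for the similarity of responses. Over 1082 named results of genes, 16719 of 18653 were the same, 1889 weaker, 45 stronger and 0 reversed. For a gene the same means an unchanged call, and a change of sign without a call in either fit also counts as the same. Named genes other than the 7 fixed ones were picked because they were called in these data, so reversals were unlikely from the start. Over 220 called list results, 2313 of 2826 were the same (still called, in the same direction), 506 weaker and 7 reversed. The stricter filter left every count within 1.5 times. A 2-fold change was recovered in 8.96% of simulated genes for the interaction of NLS with EV (17814 genes).

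With the replicate number as a block the counts were 1894 for the androgen response in WT, 2495 in NES and 1271 in NLS. Under R1881 against EV they were 2625 in WT, 2258 in NES, 1953 in NLS and 1833 in NLSKD. Against EV under vehicle they were 2058, 1474, 1571 and 1203. They were 541 and 559 for NLS against NES under R1881 and vehicle, 2 and 5 for NLS against NLSKD, 589 for NES against WT and 215 for NLS against WT. For interactions they were 22 (WT with EV), 2 (NES with EV) and 28 (NLS with EV). The block ended 1 list call, the interferon response in the androgen response of NES (median -0.24, adjusted p = 0.0632), and added 26, of which 0 were called with an estimated correlation in the fit without a block. Where the numbers pair the libraries 6 were added: p53 targets in the androgen response of WT, mesenchymal markers in NLSKD against EV under R1881, the TCA cycle and immediate early genes in NLS against NES under R1881, the unfolded protein response in NLS against NLSKD under vehicle and ribosomal proteins in NLS against WT. The other 20 included 1 for NLS against NLSKD under R1881, the androgen-induced genes (adjusted p = 0.043). It changed no other list call. Where the numbers were not taken to pair the libraries, 3 to 5 of the 6 libraries of a pairwise comparison correlated best with their own number. The cause was not tested.

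With only the compared groups in the fit, which leaves fewer libraries to estimate the spread, the counts were 836 for the androgen response in NES and 208 in NLS, 245 and 548 for NLS and NLSKD against EV under R1881, and 355 and 472 for NES and NLS against EV under vehicle. They were 5 and 11 for NLS against NES under R1881 and vehicle, 0 and 0 for NLS against NLSKD, 4 for NLS against WT, 2 for the interaction of WT with EV and 0 for NLS with EV. Every pairwise comparison with NLS is among these. The androgen responses in EV, WT and NLSKD, with as many libraries, stayed within 1.5 times, so fewer libraries alone do not account for the falls. Replicates 1 and 2 of NLS under R1881 lay farthest apart on the second principal component (66.5 and -68.2). Calls with NLS thus lean on the spread pooled over all groups. On 25 libraries the counts were 508 for the androgen response in NLS, 391 and 373 for NLS and NLSKD against EV under vehicle, 109 and 106 for NLS against NES under R1881 and vehicle, 1 for NLS against NLSKD under vehicle, 154 for NES against WT and 1 for the interaction of NLS with EV. DESeq2 gave 477 and 394 for NLS against NES, 3 and 4 for NLS against NLSKD, 446 for NES against WT, and 180 for NLS against WT. For interactions it gave 26 (WT with EV), 2 (NES with EV), 24 (NLS with EV) and 1 (NLS with NES). Without a filter the counts were 311 for NLS against NES under vehicle, 9 and 13 for NLS against NLSKD, and 155 for NLS against WT. For interactions they were 24 (WT with EV), 10 (NES with EV), 38 (NLS with EV), 5 (NLS with NES) and 4 (NLS with NLSKD).

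With the mitochondrial share as a covariate 295 genes were called for NLS against NES under vehicle, 3 for NLS against NLSKD under R1881 and 8 for the interaction of NLS with EV. RLE factors and thinned libraries each gave 1 for that interaction. limma on log2(FPKM + 1) gave 2 for NLS against NLSKD under R1881, 56 for NLS against WT. For interactions it gave 100 (WT with EV), 56 (NES with EV), 93 (NLS with EV) and 7 (NLS with NES), and on log2(FPKM + 0.1) 20, 10 and 19 for the interactions with EV. An estimated correlation kept 60 of 220 list calls. The similarity of androgen responses was 0.67 over all genes and 0.88 at a CPM of at least 5, and genes called in all 4 rescue lines numbered 444, or 227 at an adjusted p under 0.01. The cause was not tested.

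Leaving out each library in turn gave, against EV under R1881, 1035 to 1244 for WT, 723 to 976 for NES, 744 to 1081 for NLS and 675 to 820 for NLSKD. Under vehicle it gave 557 to 846 for NES, 546 to 763 for NLS and 432 to 522 for NLSKD. It gave 132 to 210 and 76 to 144 for NLS against NES under R1881 and vehicle, 0 to 2 for NLS against NLSKD under vehicle, 137 to 181 for NES against WT and 29 to 67 for NLS against WT. It gave 1 to 8 for the interaction of WT with EV, 0 to 4 for NLS with EV, and 0.63 to 0.67 for the similarity. List medians that changed sign were ribosomal proteins in NES against EV under vehicle (-0.19, from -0.35 to 0.050), ribosomal proteins in NLS against NES under R1881 (0.19, from -0.23 to 0.44, and -0.067 on 25 libraries), oxidative phosphorylation in the interaction of NLS with EV (-0.07, from -0.43 to 0.16) and mitochondrially encoded genes in the interaction of NLS with NLSKD (0.29, from -0.12 to 0.61). The cause was not tested.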

Other observations

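All tests of explanations and all splits of the libraries in this part were chosen or judged after the results were seen. Under R1881 the luminal marker list was lower than in EV in WT, NLS and NLSKD (adjusted p = 0.044, 0.0063 and 0.0074 with an estimated correlation): ACPP was lower by a log2 change of -1.68 ± 0.23, -2.03 ± 0.23 and -1.99 ± 0.23. Of the 14 members 3, 4 and 4 were lower (8, 5 and 7 adjusted over the list alone). KLK3 was called higher in WT (1.14 ± 0.31) and NLS (1.08 ± 0.31), and 1 member was higher in each of the 3 lines adjusted over the list alone. Of 19 hypoxia genes 3 were lower in both NLS and NLSKD (5 and 4 adjusted over the list alone, adjusted p = 0.039 and 0.038 with an estimated correlation), led by NDRG1 (-2.21 ± 0.33 in both), which is also an androgen-induced list member. The neuroendocrine list, with 6 tested members, was higher in NLS and NLSKD (adjusted p = 0.0071 and 0.013), and DDC, also an androgen-repressed list member, was the 1 member called over all genes. SLC7A5, which imports large amino acids, was lower than in EV in every rescue line, by -3.81 ± 0.31 in WT and -4.11 ± 0.32 in NES. In NES under vehicle 3 of the 39 ATF4 targets were lower than in EV (7 adjusted over the list alone, adjusted p = 0.043).

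A first pattern is that ATF4 targets were higher in NLS than in NES, by a score of 0.57 under R1881 (95% interval 0.43 to 0.71). The list also leaned lower in NES than in WT under R1881, with a median of -0.31. Camera called that with the preset correlation (adjusted p = 7.5e-07) but not with an estimated one (adjusted p = 0.087). The gap may therefore hold a fall in NES as well as a rise in NLS. Kinase activity of the nuclear form as the cause would lower the score in NLSKD. NLS minus NLSKD was -0.065, with an upper bound of 0.073. That argues against it for NLS and NLSKD, whose kinase activity was not measured in these data. A steady fall with MTOR mRNA over the 5 lines would put EV, with the least MTOR, at or above NLS. NLS minus EV was 0.35 (lower bound 0.21) under R1881 and 0.22 (lower bound 0.078) under vehicle. These values argue against such a fall, but another difference of the EV line could also give them. Under vehicle the list test of NLS against EV did not pass with an estimated correlation (adjusted p = 0.14). With the mitochondrial share as a covariate the list median was 0.62, and 0.56 on 25 libraries. The amount of MTOR among the rescue lines alone stays open, because MTOR was lower in NLS than in NES (-2.05), and location, which may account for the pattern, has 1 line each.

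A second pattern is that the rescue lines lay apart from EV. Kinase activity as the only cause would spare NLSKD. Yet 1227 genes called for WT under vehicle had a median signed change of 0.85 in NLSKD under R1881 (0.83 to 0.87 leaving out a library). Of these genes 91.2% changed in the same direction. The median was 1.27 in WT, 0.90 in NLS and 0.89 in NES. All 4 lines were set against the same EV libraries, so a shift of the EV line would give this too. A part played by kinase activity stays open. Of the 444 genes called in all 4 lines, 442 were called in all 4 with the mitochondrial share as a covariate and 336 on 25 libraries. Separate derivation of the EV line may account for it: 229 genes were called in all 4 lines under both treatments, and EV and its derivation cannot be told apart because each construct has 1 line.

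Other splits of the same libraries were counted for each result. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In every pairwise comparison but NLS against NLSKD under R1881, 1 of the 10 splits, the real one, gave as many genes, and the highest other count was 0 (1 for NLS against EV under R1881). Where the groups differ, mixing them widens the spread within each, so few calls in the other splits say little about chance. For NLS against NLSKD under R1881, 2 of 10 gave as many: the real count was 1 and the highest other 2008. That split parted replicate 1 of both lines from replicate 2 of both, with the libraries of replicate 3 on opposite sides. It points to a structure of the samples, and its cause was not tested. For interactions 40 splits were drawn, and they say nothing about chance. Where lines differ, relabelling carries that difference into the interaction or widens the spread, and any split reaches a real count of 0. For WT with EV 3 gave as many as the real 8 (highest other 848, with 4 of the 6 vehicle libraries relabelled), for NLS with EV 11 gave as many as the real 3 (highest other 5720, blocked 28), and for NES with EV, NLS with NES and NLS with NLSKD all 40 gave at least the real 0 (highest others 361, 5676 and 0).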
